A study of Mus musculus with 5 samples.

How the data were processed

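The series compares laser-captured epithelium of intestinal tumours from Apc1638N mice with laser-captured normal intestinal epithelium from wild-type C57Bl6/J mice. Samples were grouped by the titles in the labels into 3 tumour arrays and 2 wild-type arrays, and the numbers in those titles (16, 18 and 2, and 36 and 62) were used only as names. Per the labels' protocols, RNA was extracted with a silica column kit with on-column DNase digestion and labelled with biotin by an Affymetrix small-sample protocol. The R package affy was used, per the submitters' processing notes. The summary method, background correction and normalization were not given in the sources used here.

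The authors deposited 1 table of log2 values for 22690 probe sets on the 5 arrays, and the log2 scale was read from the values, which ran from 3.38 to 14.3. Array medians lay within 6.81 and 6.87, so the values were used as deposited with no further normalization. Many probe sets held exactly tied values. There were 1042 with the same value in all 3 tumours, 1716 with the same value in both wild-type arrays and 164 with the same value on all 5 arrays. Ties of this kind lower the estimated spread of a probe set, to 0 where all 5 arrays were tied, and the method that produced them was not given in the sources used here. Presence calls and raw intensities were not used here, so no probe set was classed as above or below background.

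The 64 Affymetrix control probe sets were set aside, which left 22626. Names came from GEO's platform annotation, in which 20380 probe sets had 1 gene symbol, 691 had several and 1555 had none. Symbols were compared through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, and 0 needed an update. Probe sets with several symbols were tested as probe sets and named no gene. Each of 12393 genes was represented by its probe set of highest mean over the 5 arrays, chosen without regard to group. No coordinates are given, because the array table names no genome build.

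Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, group as the only term), two-sided, with Benjamini-Hochberg adjustment over genes or over probe sets and a threshold of 0.05. All adjusted p-values of genes are limma's, from a fit with 3 residual degrees of freedom and a prior of 1.23. Changes are tumour minus wild type on the log2 scale, with limma's moderated standard error (SE). Folds are 2 to the power of the size of that change. The package statmod 1.5.0 was used by one alternative. Because the 5 arrays can be split in 10 ways, the smallest exact two-sided permutation p for a single value is 0.1.

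Before the data were examined, 31 gene lists with 597 members were fixed for Wnt targets, stem cells, proliferation, epithelial lineages, other cell types, gut regions, metabolism and signalling. Of these members 517 were measured, and some genes stood in more than 1 list, so that there were 498 distinct genes. Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 31 lists. Camera with an estimated correlation, and fry, were alternatives. Beside the count of called members over all genes, the count adjusted over the list alone is given.

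The genes named in the text were chosen by a rule also fixed before the data were examined. They are 16 sentinel genes, of which 13 were measured (Olfm4, Muc2 and Alpi were not analysed here), the 10 called genes with the largest rise and the 10 with the largest fall whose groups did not overlap, and up to 4 called members of each list with the largest change together with the largest called change against the majority. For a list with no called member, its 2 brightest members are named. This gave 113 genes. List members named outside this rule (Nupr1, Gata4, Muc5ac, Tff2, Col3a1 and Col1a2) were chosen after their values were seen, to complete a count or describe a list.

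The same steps were tested on simulated data in 20 runs of 12393 genes for 3 against 2 arrays. With 200 changed genes, 73.9% of 2-fold and 88.0% of 4-fold changes were recovered with 9.85 false calls per run on average. With 2695 changed genes, recovery was 89.3%, 95.6% and 98.2% for 2-fold, 4-fold and 16-fold changes, and 3.89% of calls were false. All 25 shifted lists were found, and 0.35 of 25 unshifted lists were called on average. Simulated genes were drawn independently of each other and without ties. Estimated correlations within the real lists ran from -0.13 (red blood cell genes) to 0.88 (fibroblast and matrix genes). The simulated rates therefore do not cover lists whose genes vary together, or tied probe sets.

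The alternatives fixed in advance were quantile normalization, centring each array on its median, leaving out probe sets below the 40th percentile of mean signal, eBayes with trend and robust settings, array weights, a 2-fold minimum, the mean of all probe sets of a gene, leaving out probe sets with shared targets (names ending in _s_at, _x_at or _a_at), and leaving out each array in turn. Leaving out the 2594 probe sets with values tied within a group, alone and together with each array, was added after seeing the data. Where a wild-type array was left out, 1 array remained in that group, and it was assumed to vary like the tumour arrays.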

Results

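Expression was measured on 5 Affymetrix arrays, 3 from intestinal tumours of Apc1638N mice (tumours 16, 18 and 2) and 2 from normal intestine of wild-type C57Bl6/J mice (wild types 36 and 62). The labels describe all animals as males of 8 months. Apc1638N mice carry a truncating mutation in Apc, the scaffold protein that restrains Wnt signalling, and develop tumours of the small intestine. RNA came from epithelium collected by laser capture microdissection, in which chosen cells are lifted from a tissue section under a microscope. The deposited values were log2 signals for 22690 probe sets, with array medians between 6.81 and 6.87. After control probe sets were set aside, 12393 genes were represented by their brightest probe set. Tumour arrays correlated with each other at r between 0.983 and 0.991 across probe sets, and the wild-type arrays at 0.990. Tumour and wild-type arrays correlated at 0.909 to 0.937, with tumour 2 the closest to wild type. The labels do not state that each sample came from its own animal, so p-values measure the spread between these samples, and the number of arrays limits the precision.

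The comparison asked which genes differed between tumour epithelium and normal epithelium. The largest rise of a called gene was that of clusterin (Clu), a secreted chaperone, which rose from 8.06 ± 0.03 (SD, n = 2) to 13.16 ± 0.39 (SD, n = 3), a 34.3-fold difference. The other genes with the largest rises were the protease genes Ctse (25.3-fold) and Mmp7 (13.1-fold), Wfdc18 (21.0-fold), the annexins Anxa10 (15.5-fold) and Anxa1 (15.2-fold), S100a6 (12.9-fold), the hyaluronan receptor Cd44 (12.9-fold), the homeobox gene Hoxa9 (log2 change 3.63) and the secreted Wnt inhibitor Wif1 (log2 change 3.39). No folds are given for Hoxa9 and Wif1, whose wild-type means of 5.56 and 4.02 lay below the 25th percentile of every array (6.03 or higher). With the mean of all probe sets of a gene, the log2 changes of Ctse, Cd44 and Hoxa9 were 2.28, 2.26 and 1.89, against 4.66, 3.69 and 3.63 in their brightest probe sets. Slc2a2, the glucose transporter of the basolateral membrane, fell by 5.41 on the log2 scale (SE 0.34), and the peptidase gene Enpep fell by 5.41 (SE 0.58). The falls of Rdh7, Cyp2b10, Spink1, Cyp3a25, Mme, 2010106E10Rik, Arg2 and Lct, which encodes lactase, were of similar size, with log2 changes from -4.72 to -4.41. No folds are given for these falls. Slc2a2 in tumours 16 and 2 (5.96 and 5.84) lay below the 25th percentile of every array. The same held for the tumour means of Enpep (5.68) and Mme (5.72), so the sizes of such falls are uncertain. The limma adjusted p-values of these 20 genes lay between 0.00416 and 0.0349.

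In all, 2695 of 12393 genes (21.7%) passed an adjusted p of 0.05 in limma, 1395 higher and 1300 lower in tumours. Of these, 985 also differed by at least 2-fold, 428 higher and 557 lower. The balance of directions depended on the setting, with 1450 higher and 1585 lower under median centring, 870 and 1033 with probe sets of shared targets left out, and 243 and 417 without wild type 36. Tumour and wild-type values did not overlap for 6285 genes (50.7%), where chance gives 20% on average over the possible splits of the arrays. All genes share the same 5 arrays, and the spread around that average was not computed, so the excess was not tested. Leaving out tumour 16, 18 or 2 or wild type 36 or 62, in that order, gave 719, 1033, 2380, 660 and 0 called genes. The count of 0 without wild type 62 came with 3880 genes at an unadjusted p under 0.05. When probe sets with values tied within a group were also left out, a setting chosen after seeing the data, the same 5 fits called 1507, 1830, 3069, 1544 and 1183 genes. Of the 106 genes named by rule that were called, 49, 63, 83, 24 and 0 kept their call in the fits that left out 1 array. With tied probe sets also left out, Clu, Ctse, Wfdc18, Anxa1, Mmp7, S100a6, Cd44, Slc2a2, Enpep, Rdh7 and Cyp2b10 kept their call in all 5 fits. The remaining genes with the largest changes did not, namely Anxa10, Hoxa9, Wif1, Spink1, Cyp3a25, Mme, 2010106E10Rik, Arg2 and Lct. All 2695 genes called with every array kept their direction of change in each fit that left out 1 array. Those fits share arrays with the full fit, so a kept direction is a weak check.

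**Figure D1:**
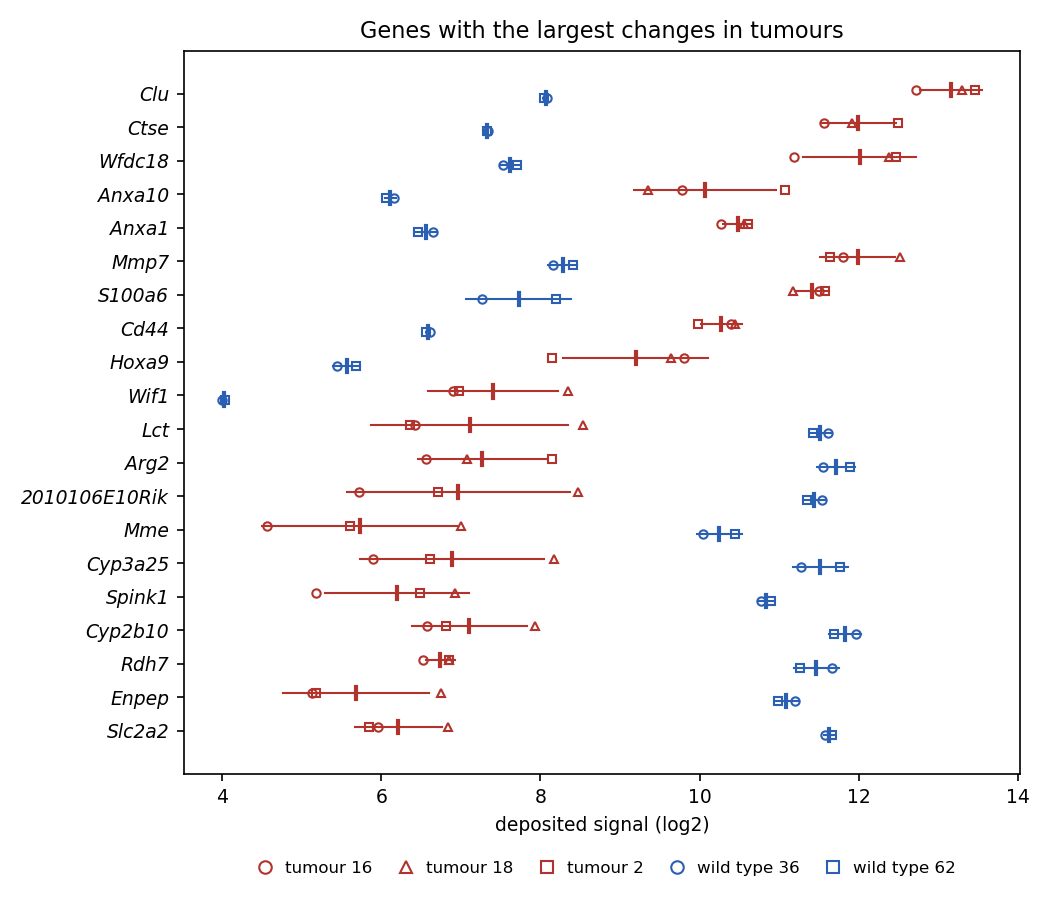
Deposited log2 signal (x axis) of the 10 genes with the largest rises and the 10 with the largest falls, one open symbol per array, with red for tumours and blue for wild type. Vertical ticks are group means and horizontal lines 1 SD, and for Clu the tumour mean was 13.16 against 8.06 in wild type.

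Wnt target genes were higher in tumours. Of 24 measured members, 13 rose, 0 fell and 11 did not pass, and 15 rose when adjusted over the list alone. Cd44 rose by 3.69 (SE 0.16), Mmp7 by 3.71 (SE 0.31), Wif1 by 3.39 (SE 0.51) and Lgr5, a receptor that marks intestinal stem cells, by 2.02 (SE 0.45). Axin2, a feedback inhibitor of the pathway, rose by 0.97 (SE 0.16), Sox9 by 1.55 (SE 0.11), Myc by 1.11 (SE 0.15) and Ascl2, a transcription factor of stem cells, by 0.91 (SE 0.16). Other probe sets differed by 0.83 for Cd44 (adjusted p = 0.0128 over probe sets), 0.22 for Axin2 (0.234), 0.68 for Sox9 (0.0381) and 1.20 and 0.46 for Ascl2 (0.0130 and 0.0576). Ccnd1, which encodes cyclin D1, differed by 0.99 with an adjusted p of 0.0667 in limma and did not pass. Its other probe sets differed by 1.57 (adjusted p = 0.0224 over probe sets) and 1.45 (0.0501). The list's camera adjusted p was 8.12e-07, and the call was lost with adjusted p = 0.427 with an estimated correlation. Among 15 intestinal stem cell genes 6 rose and 0 fell, or 8 and 0 adjusted over the list alone, led by Sox4 (2.30), Lgr5 and Prom1 (1.83). The stem cell list shares Lgr5, Ascl2 and Tnfrsf19 with the Wnt target list, so its rise is not wholly separate. That list had a camera adjusted p of 0.0219, adjusted p = 0.552 with an estimated correlation and 0.0644 without wild type 36. Leaving out tumours 16, 18 and 2 and wild types 36 and 62 in turn gave 7, 7, 9, 1 and 0 called Wnt target genes and 1, 4, 5, 1 and 0 called stem cell genes. With tied probe sets also left out, the last of these counts were 5 and 4. Lgr5 lost its call without tumour 16, tumour 2 or either wild-type array (adjusted p = 0.0911, 0.0929, 0.191 and 0.198 in limma), with a change between 1.61 and 2.28 over the 5 fits.

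Apc itself fell by 0.50 on the log2 scale (SE 0.07, adjusted p = 0.0175 in limma) in its brightest probe set. Its other probe sets differed by -0.12 (adjusted p = 0.376 over probe sets) and -0.11 (0.365). The position of these probe sets relative to the mutation was not analysed here, so the values do not check the genotype. With the mean of all probe sets the change was -0.25 (adjusted p = 0.0216 in limma). The call of the brightest probe set was lost without tumour 16 (adjusted p = 0.0709), tumour 18 (0.0719) or wild type 62 (0.0642).

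Cell division and ribosome production genes rose with the Wnt targets. Of 31 cell cycle genes, 19 rose, 0 fell and 12 did not pass, and 28 rose when adjusted over the list alone. Mcm7, a subunit of the replicative helicase, rose by 2.44 (SE 0.20), the mitotic activator Cdc20 by 2.13 (SE 0.11), the proliferation marker Mki67 by 1.27 (SE 0.08) and the ribonucleotide reductase subunit Rrm1 by 1.25 (SE 0.13). With the mean of all probe sets of a gene, Mcm7, Cdc20 and Rrm1 had changes of 1.47, 1.26 and 0.65, and Cdc20 had 1.16 with probe sets of shared targets left out. The camera adjusted p of the list was 1.27e-10, with adjusted p = 0.398 with an estimated correlation. Of 19 ribosome biogenesis genes, 12 rose and 0 fell, or 15 and 0 adjusted over the list alone. Among them were Mybbp1a (1.59), Gnl3 (1.49), the methyltransferase gene Fbl (1.31) and Ppan (1.22), and the camera adjusted p was 1.09e-07, with adjusted p = 0.427 with an estimated correlation. With probe sets of shared targets left out, the changes of Mybbp1a and Fbl were 0.57 and 0.80. Leaving out each array in the order above gave 5, 8, 17, 4 and 0 called cell cycle genes and 2, 2, 13, 2 and 0 called ribosome biogenesis genes. With tied probe sets also left out, wild type 62 left 12 and 9. Mki67, Mcm7 and Cdc20 kept their calls in every fit except the one without wild type 62.

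Absorptive enterocyte genes fell together, and none rose. Of 26 measured members, 16 fell and 10 did not pass, and 22 fell when adjusted over the list alone, with a median log2 change of -2.68. Besides Slc2a2, Enpep and Lct, the sodium-glucose transporter gene Slc5a1 fell by 4.38 (SE 0.17), and Fabp2, the intestinal fatty acid-binding protein, fell by 2.73 (SE 0.42). The camera adjusted p was 1.2e-11, with adjusted p = 0.398 with an estimated correlation. The list median lay furthest below wild type in tumour 16. Of 28 xenobiotic and retinoid genes, 24 fell and 0 rose, and 25 fell and 1 rose when adjusted over the list alone. The largest falls were those of the retinol dehydrogenase gene Rdh7 (-4.72, SE 0.17) and the cytochrome P450 genes Cyp2b10 (-4.72, SE 0.46), Cyp4f14 (-4.31, SE 0.33) and Cyp2d26 (-4.13, SE 0.51). That list had a camera adjusted p of 7.09e-13 and adjusted p = 0.398 with an estimated correlation. Fatty acid oxidation genes followed, with 9 of 21 lower and 1 higher, or 12 and 1 adjusted over the list alone (camera adjusted p = 1.49e-05, and adjusted p = 0.398 with an estimated correlation). Falls were largest for Ehhadh (-3.24, SE 0.26), Acaa1b (-3.21, SE 0.45), the transcriptional coactivator gene Ppargc1a (-2.70, SE 0.33) and Acaa2 (-2.09, SE 0.12), while Acot1 rose by 0.58. Leaving out each array in the order above gave 9, 12, 18, 5 and 0 lower enterocyte genes, 13, 16, 18, 9 and 0 lower xenobiotic genes and 5, 5, 10, 3 and 0 lower fatty acid oxidation genes. With tied probe sets also left out, wild type 62 left 10, 15 and 6. The tumour arrays also had the larger difference between 3′ and 5′ beta-actin signal, by 1.24.

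**Figure D2:**
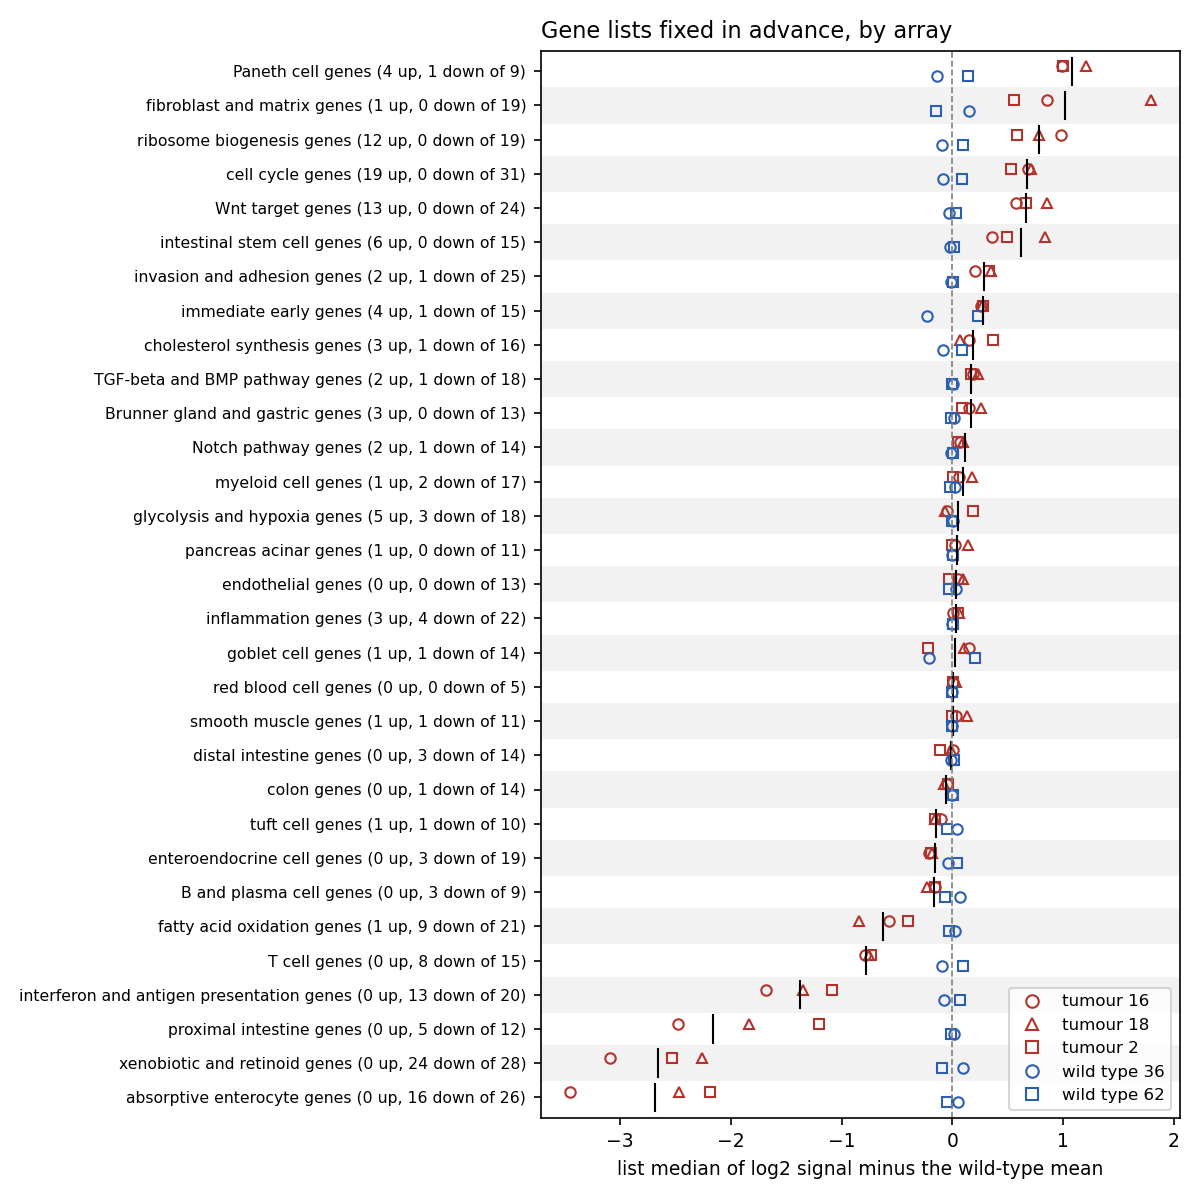
Median log2 difference from the wild-type mean over the members of each gene list (x axis), one open symbol per array and a black tick for the tumour minus wild-type median, with counts of members called higher and lower in brackets. The list medians of absorptive enterocyte genes (-2.68) and xenobiotic and retinoid genes (-2.65) lay lowest, and that of Paneth cell genes (1.08) highest.

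The secretory and sensory lineages of the epithelium did not move as one. Of 9 Paneth cell genes, 4 rose and 1 fell, or 5 and 1 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0798). It passed with median centring (0.0389), with the mean of all probe sets of a gene (0.0324) and by fry (0.0393). Lysozyme (Lyz1) rose by 1.13 (SE 0.19), Mmp7 by 3.71, the phospholipase gene Pla2g2f by 2.24 (SE 0.38) and the stress-response gene Nupr1 by 1.08, while uroguanylin (Guca2b) fell by 3.17 (SE 0.33). The change of Lyz1 was 0.46 with probe sets of shared targets left out, and that of Pla2g2f was 1.13 with the mean of all probe sets. Among 14 goblet cell genes the protease inhibitor gene Spink4 rose by 1.67 (SE 0.33), the mucus protein gene Fcgbp fell by 1.25 (SE 0.21) and 12 did not pass, with the same counts of 1 and 1 adjusted over the list alone (camera adjusted p = 0.878). Enteroendocrine cell genes had 3 of 19 lower and 0 higher over all genes and over the list alone. These were the hormone genes Sst, which fell by 0.97 (SE 0.16), Cck, which fell by 0.87 (SE 0.14), and Sct, which fell by 0.65 (SE 0.06), while Chga differed by -0.44 with an adjusted p of 0.110 in limma. That list's camera adjusted p was 0.0138, with adjusted p = 0.507 with an estimated correlation and 0.0820 without wild type 62. The call was also lost with probe sets below the 40th percentile left out (0.0580), with probe sets of shared targets left out (0.0653) and by fry (0.0508). Among 10 tuft cell genes Avil rose by 1.20 and Ltc4s fell by 0.29, and 1 rose and 2 fell adjusted over the list alone. The tuft cell list had a camera adjusted p of 0.0269, adjusted p = 0.414 with an estimated correlation, 0.0517 without tumour 2 and 0.0814 without wild type 36. It also lost its call with median centring (0.0554), with probe sets below the 40th percentile (0.121) or of shared targets (0.0886) left out, and with tied probe sets left out (0.0777). Leaving out each array in the order above gave 2, 2, 3, 0 and 0 higher Paneth cell genes and 1, 2, 2, 0 and 0 lower enteroendocrine cell genes. For Avil the call was lost without tumour 18, tumour 2 or either wild-type array, for Lyz1 without any single array, and for Spink4 and Fcgbp without any array except tumour 2.

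Genes of other gut regions were split. Of 13 Brunner gland and gastric genes, 3 rose and 0 fell, over all genes and over the list alone. These were Ctse and Anxa10, which were among the largest rises, and Gkn1 (0.80, SE 0.15), whose change was 0.28 without a call when probe sets with shared targets were left out. The gastric mucin Muc5ac differed by 0.06 and the Brunner gland peptide Tff2 by 0.71, and neither passed. The camera adjusted p was 0.0155, with adjusted p = 0.398 with an estimated correlation. Of 12 proximal intestine genes, 5 fell and 0 rose, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.00127, and adjusted p = 0.398 with an estimated correlation). Cyp2b10, Lct and the fructose transporter Slc2a5 (-2.32, SE 0.35), which also stand in other lists, fell. So did the iron exporter Slc40a1 (-2.30, SE 0.49) and the transcription factor Gata4 (-0.57). Fabp1, Ada, Apoa4 and Rbp2 of the proximal list are absorptive enterocyte genes too, so its fall is not separate from that of the enterocyte list. Among 14 distal intestine genes 3 fell, namely Ces1f (-4.01, SE 0.34), Slc51a (-2.72, SE 0.29) and Clec2h (-2.02, SE 0.32). The distal list median was -0.01 and its mean -0.61, and its camera adjusted p was 0.321, with 0.0177 by fry. Among 14 colon genes the chloride-bicarbonate exchanger Slc26a3 fell by 2.00 and 13 did not pass (camera adjusted p = 0.344). Leaving out each array in the order above gave 1, 3, 2, 0 and 0 higher Brunner gland and gastric genes, 1, 3, 5, 1 and 0 lower proximal genes and 1, 2, 3, 1 and 0 lower distal genes.

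Interferon and antigen presentation genes were lower in tumours. Of 20 measured members, 13 fell and 0 rose, or 14 and 0 adjusted over the list alone, with a median of -1.38. They included the class I light chain B2m (-2.66, SE 0.35), the immunoproteasome subunit Psmb9 (-2.57, SE 0.12) and the class II genes H2-Ab1 (-2.55, SE 0.33) and H2-Aa (-2.36, SE 0.54). The camera adjusted p was 5.07e-08, with adjusted p = 0.398 with an estimated correlation. With probe sets of shared targets left out, 4 of 11 measured members fell and the median was -0.27 (camera adjusted p = 0.000724), and with the mean of all probe sets of a gene it was -0.92. T cell genes moved the same way, with 8 of 15 lower and 0 higher, or 10 and 0 adjusted over the list alone (camera adjusted p = 1.14e-05, and adjusted p = 0.398 with an estimated correlation). The largest falls were those of the chemokine Ccl5 (-3.40, SE 0.26), granzyme A (Gzma, -2.84, SE 0.31), Klrd1 (-2.00, SE 0.18) and the T cell receptor subunit Cd3g (-1.41, SE 0.13). Of 9 B and plasma cell genes, 3 fell and 0 rose, or 5 and 0 adjusted over the list alone, namely Jchain (-2.99, SE 0.36), Cd74 (-2.34) and Igha (-1.99, SE 0.45). That list had a camera adjusted p of 0.0099, adjusted p = 0.483 with an estimated correlation, 0.0768 without tumour 2 and 0.0584 without wild type 36. Its call was also lost by fry (0.0569) and with probe sets of shared targets left out (0.135), where 1 of 6 members fell. Of 17 myeloid cell genes, 1 rose (Cd14, 0.94) and 2 fell, the pan-leukocyte gene Ptprc (-1.94, SE 0.13) and Ctss (-1.59), and the list did not pass (camera adjusted p = 0.793). Inflammation genes went both ways, with 3 of 22 higher, 4 lower and a camera adjusted p of 0.988. Lcn2, an antimicrobial siderophore-binding protein, rose by 2.94 (SE 0.46), and the antimicrobial lectin Reg3g (-2.52, SE 0.35), Il18 (-1.97) and Nfkbiz (-1.51) fell. The Lcn2 call was lost without tumour 18 or tumour 2, that of Il18 without tumour 16 or tumour 18, and that of Nfkbiz without tumour 16. Reg3g kept its call without each tumour in turn. Lcn2, Il18, Nfkbiz and Reg3g all lost their calls without either wild-type array. Leaving out each array in the order above gave 7, 10, 9, 3 and 0 lower interferon and antigen presentation genes, 3, 4, 5, 5 and 0 lower T cell genes and 0, 1, 1, 0 and 0 lower B and plasma cell genes. With tied probe sets also left out, wild type 62 left 6, 6 and 2.

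Of 19 fibroblast and matrix genes, only decorin (Dcn) passed, with a rise of 2.60 (SE 0.52), and 0 passed adjusted over the list alone. The list median was 1.02 above wild type, or 0.62 without tumour 18, and per tumour it was 0.86 in tumour 16, 1.79 in tumour 18 and 0.55 in tumour 2. Col3a1 differed by 2.32 and Col1a2 by 2.32 without passing. The camera adjusted p was 0.00184, with adjusted p = 0.636 with an estimated correlation and 0.177 by fry. Dcn lost its call without tumour 16, tumour 18 or either wild-type array. Among 11 smooth muscle genes Acta2 rose by 1.22 (SE 0.19) and Mylk fell by 1.68 (SE 0.16), or 2 and 1 adjusted over the list alone, with a camera adjusted p of 0.820, and the Acta2 value was -0.0056 when probe sets with shared targets were left out. With the mean of all probe sets of a gene, Acta2 had 0.61 and Mylk -0.94. Endothelial genes (13 measured), red blood cell genes (5) and pancreas acinar genes (11) did not pass as lists, with camera adjusted p-values of 0.610, 0.806 and 0.813. Among them only the elastase gene Cela1 was called, with a rise of 2.26 (SE 0.36) that was lost without tumour 16, tumour 18 or either wild-type array. The endothelial genes Kdr and Plvap differed by -0.000567 and 0.04, and the red cell genes Alas2 and Slc4a1 by 0.30 and 0.01. Epcam, an adhesion molecule of all intestinal epithelial cells, differed by -0.48 with an adjusted p of 0.0858 in limma.

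Several metabolic and signalling lists did not pass, although single members were called. In glycolysis and hypoxia 5 of 18 genes rose and 3 fell, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.736). The glucose transporter Slc2a1 rose by 1.65 (SE 0.20), the hexokinases Hk2 by 1.48 (SE 0.20) and Hk1 by 1.11 (SE 0.06), and Pfkl by 1.07 (SE 0.07), while Pkm fell by 0.96 (SE 0.21). With probe sets of shared targets left out Slc2a1 had 0.44, and with the mean of all probe sets Hk1 had 0.58 and Pfkl 0.65. The Pkm call was lost with quantile normalization (adjusted p = 0.0584 in limma) and in every fit that left out 1 array except the one without wild type 36. Its change was -1.29 without wild type 36 and -0.64 without wild type 62. In cholesterol synthesis 3 of 16 rose, namely Fdft1 (1.53), Mvd (1.01) and Lss (0.70), Sc5d fell by 0.79, and the camera adjusted p was 0.169. Fdft1, Mvd and Lss lost their calls when probe sets with shared targets were left out, with changes of 0.64, 0.14 and 0.28. With the mean of all probe sets, the changes of Fdft1, Mvd and Sc5d were 0.56, 0.58 and -0.41. Notch pathway genes had Notch2 (1.33) and Notch3 (0.30) higher and the ligand Dll1 lower (-0.71) among 14, with a camera adjusted p of 0.169. Notch3 lost its call with probe sets of shared targets left out (0.0253, adjusted p = 0.666 in limma) and with the mean of all probe sets (0.16, 0.0524), and in every fit that left out 1 array except tumour 2. TGF-beta and BMP pathway genes had the receptor Tgfbr2 (1.39) and Smad6 (0.48) higher and Bmp2 lower (-1.34) among 18, with a camera adjusted p of 0.223 and 0.0174 by fry. Among 25 invasion and adhesion genes the claudin Cldn2 (2.49, SE 0.20) and the membrane protease Mmp14 (1.91, SE 0.19) rose, and Cldn15 fell by 2.28 (SE 0.17), with a camera adjusted p of 0.0916 and 0.0260 by fry. Immediate early genes had 4 of 15 higher, with Hspa1b (1.67), Egr1 (0.88) and Ier2 (0.59) leading, and Zfp36 lower (-0.97), with a camera adjusted p of 0.0914. The change of Hspa1b was 0.28 with probe sets of shared targets left out. With the mean of all probe sets it was 0.83, and Notch2, Tgfbr2, Cldn2 and Mmp14 had 0.68, 0.43, 1.29 and 0.98. Without wild type 62 the immediate early list passed (camera adjusted p = 0.00378), as did cholesterol synthesis (0.0324). The former also passed without tumour 16 (0.0475) and the latter with the mean of all probe sets of a gene (0.0303). Lss, Dll1, Tgfbr2, Egr1, Ier2 and Zfp36, and Igha and Clec2h from the lists above, lost their calls in every fit that left out 1 array, while Hk1, Pfkl, Cldn15 and Hspa1b lost theirs only without wild type 62.

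RNA quality moved with the groups. Affymetrix arrays carry control probe sets at the 5′ end, the middle and the 3′ end of beta-actin and Gapdh, and a larger 3′ minus 5′ difference marks shorter or less complete labelled transcripts. For beta-actin the difference was 4.15 ± 0.13 (SD, n = 3) in tumours and 2.91 ± 0.57 (SD, n = 2) in wild type, 1.24 apart, with an exact two-sided permutation p of 0.1. For Gapdh it was 4.64 ± 0.17 and 3.84 ± 0.24, 0.80 apart, with an exact permutation p of 0.1. This is the smallest p that the 10 splits of 3 against 2 arrays allow. The 5′ probe sets accounted for the gap, with beta-actin at -1.25 and Gapdh at -0.83 in tumours relative to wild type. The 3′ probe sets differed by -0.02 for both genes.

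**Figure D3:**
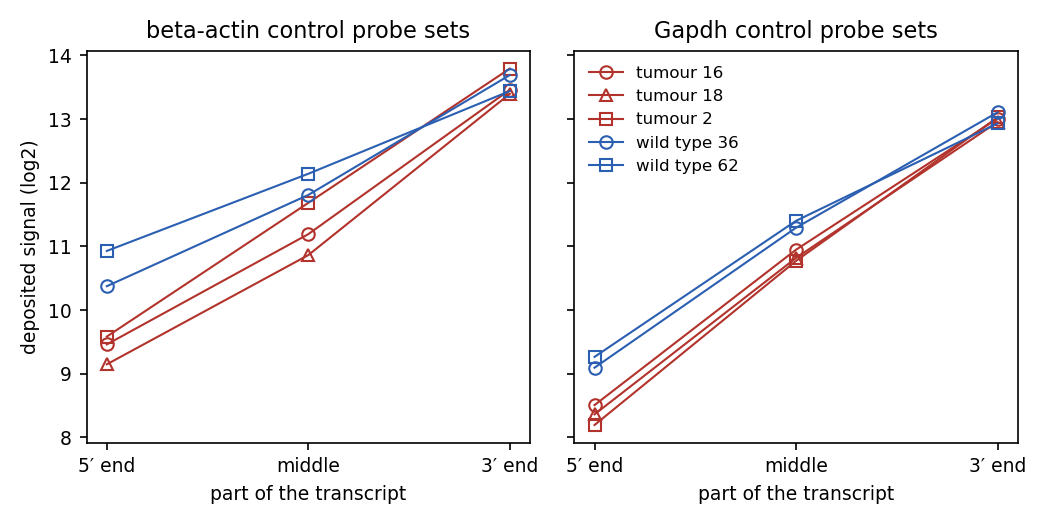
Deposited log2 signal (y axis) of the control probe sets at the 5′ end, middle and 3′ end (x axis) of beta-actin (left) and Gapdh (right), one line per array, with red for tumours and blue for wild type. The 3′ minus 5′ difference of beta-actin averaged 4.15 in tumours and 2.91 in wild type.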

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

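No paired analysis was possible because the groups share no replicate numbers. The pseudocount alternatives were not run, since the values were already log2. Leaving out tied probe sets, alone or with an array, was chosen after seeing the data. Gene counts ranged from 1903 to 3064 under the other settings, 870 of the 1903 being higher with probe sets of shared targets left out. A 2-fold minimum left 1493 probe sets (677 higher, 816 lower) of 4139 and 985 genes (428 higher, 557 lower). Leaving out 1 array gave 0 to 3424 probe sets (0 to 1875 higher, 0 to 1549 lower), 0 to 2380 genes (0 to 1295 higher, 0 to 1085 lower) and 12 to 16 gene lists. With tied probe sets also left out it gave 1703 to 4790 probe sets (846 to 2637 higher, 857 to 2153 lower), 1183 to 3069 genes (567 to 1664 higher, 616 to 1405 lower) and 12 to 16 lists. The lowest gene and probe set counts were without wild type 62. Removing ties raised limma's prior degrees of freedom from 0.737 to 1.31 in that fit and equally in the fit without wild type 36. The lowest list counts were without wild type 36. The gap in beta-actin 3′ minus 5′ signal ranged from 0.84 (without wild type 62) to 1.64 (without wild type 36). Of 31 lists, 15 were called by camera at the preset correlation, 0 with an estimated correlation and 16 by fry. Acta2 reversed, to -0.0056, with probe sets of shared targets left out, and the cause was not tested. Lgr5, Dll1 and Egr1 lost their calls in that setting too (adjusted p = 0.0539, 0.0546 and 0.0569 in limma). Of 113 named genes, Ccnd1 gained a call under 6 settings that kept all arrays, and 9 lost theirs with array weights (Lgr5, 2010106E10Rik, Avil, Lss, H2-Aa, Dll1, Bmp2, Egr1 and Ier2). Quantile normalization and centring shifted the median gene change by less than 0.1, to -0.007 and -0.03.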

Other observations

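The comparison of gene families and the tests of explanations in this part were chosen after the results they measure were seen. In those tests, SEs of medians, and of differences between medians, were taken over list genes as if these were independent. They hold no error between arrays and may be too small. The SE of the tumour coefficient was taken over arrays. Besides the fixed lists, 221 gene families sharing the opening letters of their symbols (8 to 100 measured genes each) were compared with camera in limma. Members of the fixed lists were not removed from these families. Genes of the translation machinery led those that were higher in tumours. Of 24 genes with symbols opening in Rpl, most of which encode proteins of the large ribosomal subunit, 19 rose and 0 fell (median 0.78, camera adjusted p = 8.49e-08), and of 26 opening in Rps 14 rose and 0 fell (median 0.52, camera adjusted p = 6.88e-05). The Rps group holds small-subunit genes together with 4 S6 kinase genes and 1 pseudogene, none of which was called. Leaving out tumour 16, 18 or 2 or wild type 36 or 62, in that order, gave 6, 9, 14, 4 and 0 called Rpl genes and 0, 3, 10, 6 and 0 called Rps genes, with positive medians each time. Ribosomal protein genes have near-identical processed copies that probe sets can share, so single members are uncertain. Among 8 Cct genes, subunits of a cytosolic chaperonin that folds actin and tubulin, 5 rose and 0 fell (camera adjusted p = 0.00661), led by Cct3 (1.50), and the same 5 fits called 2, 3, 4, 2 and 0. All families lost their calls with an estimated correlation, at adjusted p = 0.843 for each family named here. Medians of the families named here kept their sign under quantile normalization and median centring.

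Annexins, which bind membranes in a calcium-dependent way, had 5 of 11 members higher and 0 lower (camera adjusted p = 0.00990), namely Anxa10 (3.96), Anxa1 (3.92), Anxa8 (3.04), Anxa3 (2.25) and Anxa5 (1.54). On the other side, carboxylesterases (Ces) had 5 of 9 lower and 0 higher (median -1.42, camera adjusted p = 0.000783), and Ndufa genes of mitochondrial complex I had 5 of 12 lower and 0 higher (median -0.50, camera adjusted p = 0.00418). All 3 families lost their calls with an estimated correlation (adjusted p = 0.843). Anxa10, Ces1f and Ces2a, which are among the called members, also stand in the fixed lists. Leaving out each array in the order above gave 3, 4, 5, 2 and 0 higher annexins, 3, 3, 4, 4 and 0 lower carboxylesterases and 1, 2, 7, 1 and 0 lower Ndufa genes.

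Absorptive enterocyte genes fell in tumours with a median log2 change of -2.68, and unevenly, most in tumour 16. Greater 3′ bias of tumour RNA may contribute to the fall. With the beta-actin 3′ minus 5′ difference as a covariate, the tumour coefficient of the list median over the 5 arrays was -3.42 (SE 1.40, 95% interval -9.43 to 2.59). That difference was at least 3.9994 in tumours and at most 3.32 in wild type. Wild type 36, at 3.32 against 2.51 in wild type 62, had a list median 0.103 above that of wild type 62. Tumour 16 had the smallest difference of the tumours, against 4.25 in tumour 18 and 4.21 in tumour 2. Its list median was the lowest, at -3.45 against -2.47 and -2.19. Such comparisons within a group rest on single arrays. The 5′ control probe sets differed by -1.25 (beta-actin) and -0.83 (Gapdh), and the 3′ probe sets by -0.02. The enterocyte list median fell further than these in every tumour. This argues against 3′ bias of the size seen in these controls as the whole of the fall. How far the enterocyte probe sets lie from the 3′ end was not analysed. The 3′ minus 5′ difference did not overlap between groups. A partial contribution of 3′ bias and a change in the tumour epithelium therefore cannot be told apart. Unequal shares of normal mucosa in the captures may contribute to the unevenness. Over all 26 members, the median share of normal mucosa needed above tumour 16 was 3.58% (SE 3.06%) in tumour 18 and 8.92% (SE 3.13%) in tumour 2. The lower quartile of the ratio of tumour to wild-type signal was 11.8% and 10.6%. It is a loose limit, since a share cannot exceed this ratio in any member. Members with the largest falls allow less, such as Slc2a2 (5.84 in tumour 2 against a wild-type mean of 11.62) and Enpep (5.18 against 11.09). In tumours 18 and 2, 5 and 4 of the 26 members lay below tumour 16, which added mucosa alone would not give. The wide errors, and a limit set by few members, leave a contribution of unequal shares undecided. A difference between tumours in differentiation, and the unlabelled position of each sample along the gut, stay open and untested.

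The median of 19 fibroblast and matrix genes was 1.02 above wild type (0.62 without tumour 18), with 1 member called, and the list lost its call by fry and with an estimated correlation. Between tumours, tumour 18 lay above the mean of tumours 16 and 2 by a median of 1.13. Stromal cells in the tumour captures, most in tumour 18, are a candidate explanation, although laser capture was meant to take epithelium only. Other stromal cells might then be more abundant in tumour 18 too, and over 24 smooth muscle and endothelial genes the median of the same difference was 0.104 (SE 0.0506). That value is positive but far below the fibroblast value, and fibroblasts can be captured without vessels or muscle, so it decides nothing. Expression of the matrix genes by the tumour cells themselves was not tested.

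Interferon and antigen presentation genes fell together with T cell genes. Fewer lymphocytes in the tumour captures may account for part of this, because both lists hold genes that lymphocytes express. Among genes with a wild-type signal above 8, the median change was -2.22 over 13 interferon and antigen presentation genes and -2.00 over 5 T cell genes, a difference of -0.22 (SE 0.68). With bright B and plasma cell genes outside the interferon list added, the median over 8 lymphocyte genes was -2.00 and the difference -0.22 (SE 0.58). The size of these errors keeps fewer lymphocytes and lower expression in the epithelium from being told apart. Lower expression in the tumour epithelium, where the design names the group, was not tested separately.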
